A study of Sphingomonas melonis TY with 21 samples.

How the data were processed

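RNA-seq libraries of Sphingomonas melonis TY were read from 1 deposited table of FPKM values (fragments per kilobase, scaled by library size) for 4569 features in 21 libraries, with coordinates, strand and length. Per the submitters' processing notes, the tools used included HTSeq (0.6.1), Bowtie2 (2.2.3) and DESeq (no version given); the genome build, the strand setting of the counting and the sequence's source are not given in the sources used here. Per the labels' protocols, ribosomal RNA was depleted before sequencing. Libraries were grouped by NaCl level and time from their treatment labels, 3 per group, and the table's columns were matched to them by title. The treatment text speaks of 18 samples in 6 treatments, and 21 samples in 7 groups are labelled.

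The deposited FPKM values were tested for what they hold. FPKM times length was a whole multiple of 1 step per library for 100% of values (tolerance 0.01 read), which gave whole reads and a library size for each library. Those library sizes equalled median-of-ratios size factors of the recovered reads times 2645360 in every library, so the deposited FPKM already carry that scaling, and the median-of-ratios rescaling chosen beforehand moved almost nothing. Gene-model lengths were multiples of 3 in 100% of cases and hold no untranslated regions, so coding length is meant. Without stated strand use, features that overlap on opposite strands are uncertain.

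Features with a mean FPKM of at least 1 over all libraries (4356) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a mean trend), all 21 libraries in 1 fit. A feature counted as changed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. Fold changes are on the log2(FPKM + 1) scale and understate those of low features. Contrasts were 1% and 2% against 0% NaCl at 10 and 30 min, 2% against 1%, the difference of each effect between times, and 0% NaCl at 10 and 30 min against 0 min. These tests, the other settings chosen beforehand and the rule for naming features were fixed before the data were examined. By that rule, with no names in the table, at most 2 features that rose and 2 that fell are named per contrast, those with the largest changes among features of at least 20 FPKM in the higher group whose 3 and 3 libraries did not overlap (the last condition was not applied to differences of effects). The 37 gene lists fixed beforehand could not be matched, because the table pairs no ID with a name. All 21 columns of library values were used.

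Other settings chosen beforehand were pseudocounts of 0.1 and 5, no filter and a mean of at least 10 FPKM, TPM, median-of-ratios factors, only the groups of the contrast, no limit on the fold, the replicate number as a block, and each library left out. Alternatives chosen after seeing the data were limma-voom on recovered reads, limma without the mean trend, gene models alone, the spread of each library as a covariate, and subtraction of each library's 20th percentile of gene-model FPKM followed by rescaling on features averaging at least 200 FPKM, with a pseudocount of 20.

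On simulated reads for 2% against 0% NaCl at 10 min, with 200 planted changes among 4353 tested features, 31.3% of 2-fold, 74.6% of 4-fold and 98.5% of 8-fold changes were recovered, with 7 false calls among 4153 unchanged features. A planted 2-fold change lies on the limit of 1 on the log2 scale, which itself holds down the share recovered (median absolute log2 estimate 0.945). The simulation drew features independently around the mean reads of 0% NaCl at 10 min. It held no difference between libraries in spread or background, so it does not cover false calls from these. With 2248415 to 3129705 reads per library, a feature of 1 kb at 1 FPKM holds only a few reads. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.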

Results

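RNA was sequenced from Sphingomonas melonis TY, an alphaproteobacterium, grown in LB and exposed to sodium chloride. The 21 libraries fell into 7 groups of 3: 0% NaCl at 0, 10 and 30 min, and 1% and 2% NaCl at 10 and 30 min. The labels do not say whether these percentages come on top of the salt in the medium. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom of at least 5.06), and Pearson's r of log2 values between them lay between 0.896 and 0.988. The table lists 4569 features on 1 sequence: 4119 gene models, 360 further features with IDs such as Novel00327 (called further features here) and 90 with sRNA IDs. It pairs no ID with a gene name, so features are given by ID and coordinates, and groups of genes by position. The reads recovered from the values summed to between 2248415 and 3129705 per library, and 1 read in a feature of 1 kb was worth 0.205 to 0.797 FPKM.

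The libraries differed in how widely their gene values were spread. The log2 ratio of the 80th to the 20th percentile of gene-model FPKM was 1.50 ± 0.27 (SD, n = 9) at 0% NaCl and 3.02 ± 0.87 (SD, n = 12) with NaCl (exact permutation test over 293930 splits, two-sided p = 0.000119, which treats times and doses as exchangeable). Within 1% NaCl at 10 min it ranged from 2.02 to 4.50, the widest range of the 7 groups. Replicate 3 had the most reads in all 7 groups and the widest spread in 6 of them, counted after the data were seen. The labels give no batch or date to set beside this.

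**Figure D1:**
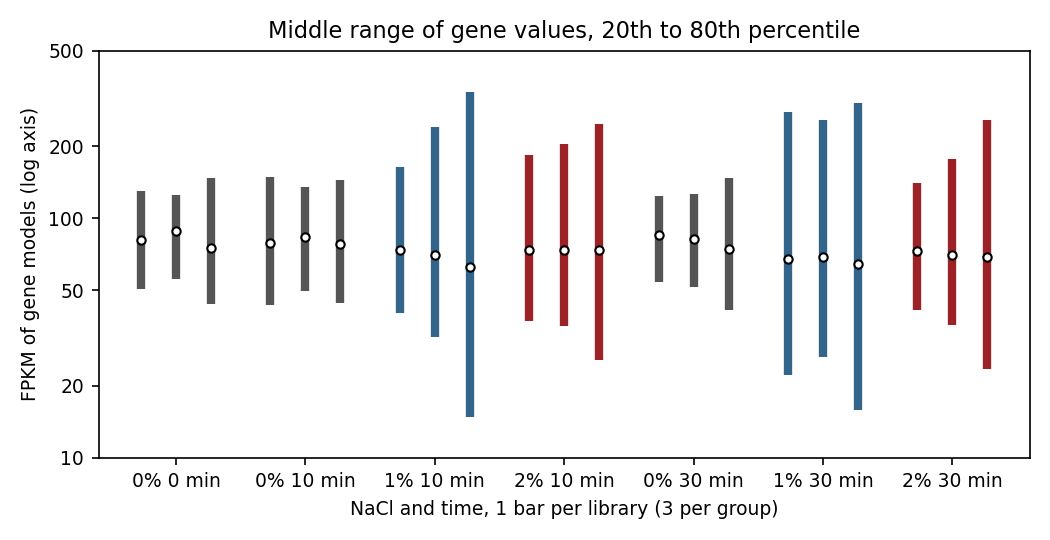
Bars span the 20th to 80th percentile of gene-model FPKM (log axis) in each of the 21 libraries, and circles mark the median. The 20th percentile lay between 14.8 and 55.8 FPKM and the 80th between 124 and 335 FPKM.

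At 10 min of 2% NaCl, the largest rises were in 2 neighbouring gene models on the plus strand. Sphingomonas.melonisTY_GM001617 (1557139 to 1557759) rose from 109 ± 7.61 FPKM (SD, n = 3) at 0% NaCl to 26201 ± 11413 FPKM (SD, n = 3), a log2 change of 7.81 (SE 0.38, adjusted p = 1.34e-10). Sphingomonas.melonisTY_GM001618 (1557756 to 1558058), which overlaps its end, rose by 7.42 (SE 0.43, adjusted p = 9.46e-10). The named falls were Sphingomonas.melonisTY_GM003078 (3106766 to 3107179, minus strand) and Sphingomonas.melonisTY_GM002127 (2121970 to 2122896, plus strand), at -3.52 (SE 0.53) and -3.41 (SE 0.29). The first rested on 34 to 51 reads per library at 0% NaCl and 0 to 4 at 2%. The second stood at 327 ± 51.5 FPKM at 0% NaCl at 10 min but at 67.7 ± 6.89 FPKM at 0 min (SD, n = 3 each), so its fall was measured against a raised control. In all, 983 of 4356 tested features rose and 483 fell with limma. Rescaled to the same sum in each library (TPM), 666 rose and 742 fell.

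At 1% NaCl and 10 min the same neighbours led, with log2 changes of 5.43 (SE 0.38) for Sphingomonas.melonisTY_GM001617 and 5.05 (SE 0.43) for Sphingomonas.melonisTY_GM001618. The former reached 5025 ± 1878 FPKM (SD, n = 3). Both overlap Novel00170 on the opposite strand. The counting is not stated to use strand, so how far reads of that feature were counted for them is not known. Sphingomonas.melonisTY_GM002029 (2012264 to 2012386, plus strand) fell by 3.82 on the log2 scale (SE 0.60) and Sphingomonas.melonisTY_GM002064 (2048434 to 2048592, plus strand) by 3.48 (SE 0.82), from 6 to 12 and 12 to 22 reads per library at 0% NaCl to 1, 0 and 0 and to 9, 0 and 0 reads in replicates 1 to 3 at 1%, so both folds rest on libraries at zero. In all, 926 features rose and 338 fell. Without replicate 1 of 1% NaCl at 10 min, the library with the narrowest spread in its group, the count went from 1264 to 2044, and in the TPM rescale 481 rose and 2014 fell. The falls varied more than the rises: 130 to 900 fell and 745 to 1144 rose with 1 library left out, and 99 fell and 806 rose when only the 2 groups compared were fitted. Over the 3 NaCl levels at 10 min, 2764 features differed by limma's F-test at an adjusted p under 0.05 with no limit on the fold.

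By 30 min at 1% NaCl, the 2 largest rises were in gene models that were already abundant. Sphingomonas.melonisTY_GM001575 (1514818 to 1515402, minus strand) went from 697 ± 454 FPKM to 93164 ± 10486 FPKM (SD, n = 3 each; log2 change 7.25, SE 0.67, adjusted p = 3.31e-08). Sphingomonas.melonisTY_GM000128 (83285 to 84490, minus strand) went from 1596 ± 918 FPKM to 148320 ± 14898 FPKM (SD, n = 3 each; log2 change 6.69, SE 0.67). Each is covered from end to end by a feature on the opposite strand, Novel00167 and Novel00013. Sphingomonas.melonisTY_GM002974 (3004793 to 3004873, plus strand) fell by 5.08 (SE 0.79), from 20 to 46 reads per library to 0 to 3. No read was listed for Sphingomonas.melonisTY_GM004053 (4082501 to 4082629, minus strand) in the 3 libraries at 1% NaCl; against a floor of 3 reads per library it was at least 1.97-fold lower than the 31.5 FPKM at 0%. In all, 1156 features rose and 1054 fell, and 422 rose and 2963 fell in the TPM rescale. Among gene models under 20 FPKM at 0% NaCl the median log2 change was -1.02, and among those of 500 FPKM or more it was 1.46; at 2% NaCl and 30 min the same medians were -0.31 and -0.05.

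At 2% NaCl and 30 min, Sphingomonas.melonisTY_GM001617 still led, with 6541 ± 3590 FPKM against 80.2 ± 1.93 FPKM (SD, n = 3 each; log2 change 6.19, SE 0.38, adjusted p = 7.36e-09). The next largest rise was in Sphingomonas.melonisTY_GM001309 (1234667 to 1234747, plus strand; 6.09, SE 0.38), an 81-base coding length that lies opposite sRNA00084. Sphingomonas.melonisTY_GM000527 (449933 to 453007, minus strand) fell from 2012 ± 1184 FPKM to 148 ± 46.1 FPKM (SD, n = 3 each; log2 change -3.64, SE 0.47), and Sphingomonas.melonisTY_GM001633 (1572593 to 1572772, minus strand) fell by 3.80 (SE 0.65). In all, 978 features rose and 436 fell, against 642 and 1349 in the TPM rescale. The F-test over the 3 NaCl levels at 30 min gave 3356 features. The TPM rescale moved the median log2 change of all tested features from -0.15 to -1.06 (1%, 10 min), from -0.07 to -0.57 (2%, 10 min), from -0.04 to -1.78 (1%, 30 min) and from -0.17 to -0.94 (2%, 30 min). Named features kept their direction in it. Subtraction of a background, chosen after the data were seen, also gave more falls than rises: 299 rose and 1521 fell (1%, 10 min), 639 and 1276 (2%, 10 min), 445 and 2165 (1%, 30 min), and 484 and 2019 (2%, 30 min).

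**Figure D2:**
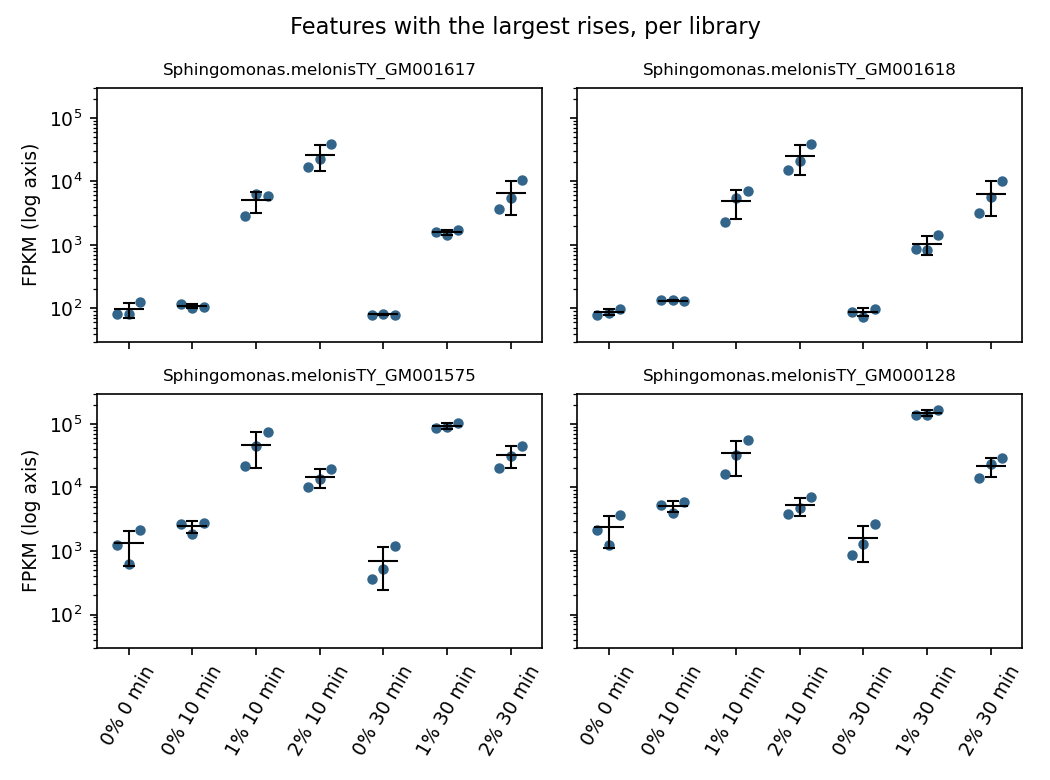
FPKM (log axis) of 4 gene models in each library (points), with the mean and SD of the 3 libraries of each group. Sphingomonas.melonisTY_GM001617 and Sphingomonas.melonisTY_GM001618 stood highest at 2% NaCl and 10 min, and Sphingomonas.melonisTY_GM001575 and Sphingomonas.melonisTY_GM000128 at 1% NaCl and 30 min.

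**Figure D3:**
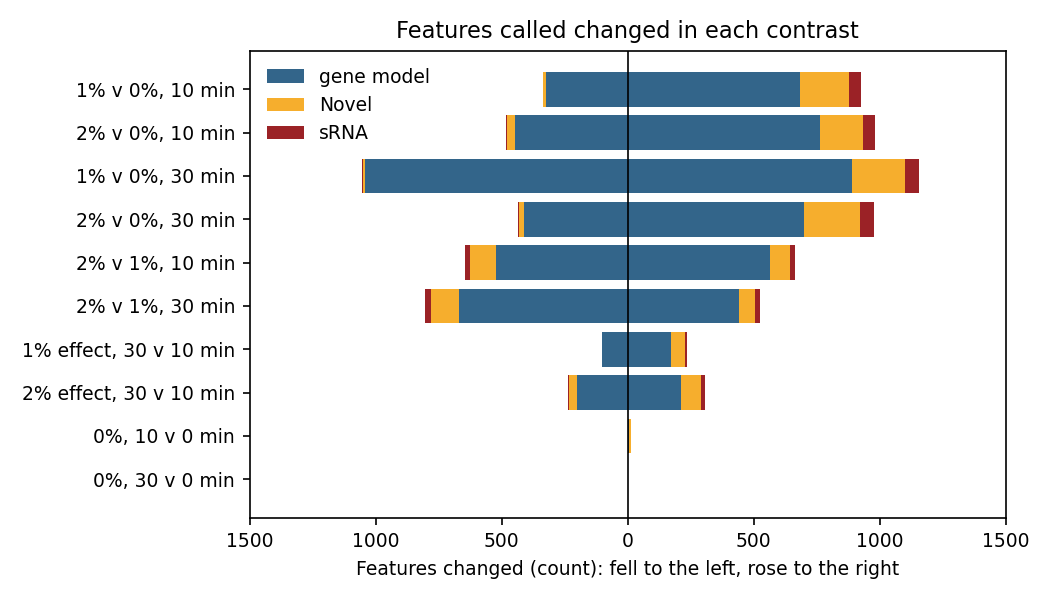
Bars give the number of features that rose (right) and fell (left) in each contrast, coloured by the kind of ID. Changes with NaCl numbered 1264 to 2210 features per contrast, and changes over time at 0% NaCl 13 and 0.

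Neighbouring genes changed together. Runs of at least 5 adjacent gene models on 1 strand, all changed in the same direction, numbered 9 (1%, 10 min), 11 (2%, 10 min), 37 (1%, 30 min) and 14 (2%, 30 min). Shuffling the calls among tested gene models 1000 times gave at most 3, 3, 9 and 3 runs (permutation p = 0.000999 for each, the smallest these shuffles can give). The rule for runs was chosen after the data were seen, and the 2 longest runs each way per contrast are described. A run of 14 genes at 2155298 to 2168804 (minus strand) rose at 2% NaCl and 10 min by a median log2 of 1.99, and at 30 min the median was -0.10, with the 2% effect lower at 30 than at 10 min in 11 of the 14. A run of 10 genes at 3766670 to 3769965 (minus strand) rose at 1% NaCl by medians of 2.70 at 10 min and 2.23 at 30 min; at 2% the medians were 0.71 and -0.18, and all 10 were lower at 2% than at 1% at both times. Another of 7 genes at 2488805 to 2491791 (minus strand) rose at 2% NaCl and 10 min by a median of 1.72.

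Other runs were chosen at 30 min. Of 2 that fell at 2% NaCl, 12 of 13 and 6 of 9 genes also passed as fallen at 1%. In the first, 13 genes at 926473 to 937236 (plus strand) had median log2 changes of -1.60 at 2% and -2.17 at 1% NaCl, against -0.46 and -0.14 at 10 min. In the second, 9 genes at 333966 to 340893 (plus strand) stood at medians of 0.66 and 0.69 at 10 min, at 2% and 1% NaCl, and at -1.39 and -1.31 at 30 min; the effect at 30 min was lower than at 10 min in 9 of them at 2% and in 8 at 1%. Of the runs that rose, 9 genes at 1386206 to 1392266 (plus strand) did so at 30 min at 2% NaCl by a median of 2.43, where 6 had a higher effect than at 10 min. Another 8 genes at 2174337 to 2180057 (minus strand) rose at 1% NaCl and 30 min by a median of 2.08, and 7 of them rose at 2%; at 10 min the medians were already 1.50 at 1% (5 of 8 called) and 1.61 at 2% (6 of 8), and the effect differed between times in 0 of 8 at 1% and 1 of 8 at 2%. At 1% NaCl and 30 min, 13 genes at 3105396 to 3114189 and 11 at 2777316 to 2789624 (both minus strand) fell by medians of 2.07 and 1.92; at 10 min their medians were -1.41 (5 of 13 called) and -0.91 (4 of 11), and the effect differed between times in 0 and 2 of them. With the spread of each library as a covariate, an alternative chosen after the data were seen, the medians of these last 2 runs were 0.03 and -0.25, while those of the 13 genes at 926473 to 937236 stayed at -1.89 (1%) and -1.72 (2%). Of the runs that rose, the medians fell to 0.76 at 3766670 to 3769965 (1%, 30 min; 2 of 10 still called), 1.00 at 2174337 to 2180057 (1%, 30 min; 4 of 8) and 0.93 at 2488805 to 2491791 (2%, 10 min; 3 of 7), while all 10 genes at 3766670 to 3769965 were still called at 1% and 10 min. In the TPM rescale the median of the 9 genes at 333966 to 340893 turned from 0.69 to -0.25 at 1% NaCl and 10 min, and that of the 14 genes at 2155298 to 2168804 from 0.70 to -1.08 at 1% and 30 min, where only 1 of the 10 genes at 3766670 to 3769965 and 3 of the 8 at 2174337 to 2180057 still rose. At 2% NaCl the rescale still called 11 of the 14 genes at 2155298 to 2168804 and 4 of the 7 at 2488805 to 2491791 at 10 min, and 6 of the 9 at 1386206 to 1392266 at 30 min.

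**Figure D4:**
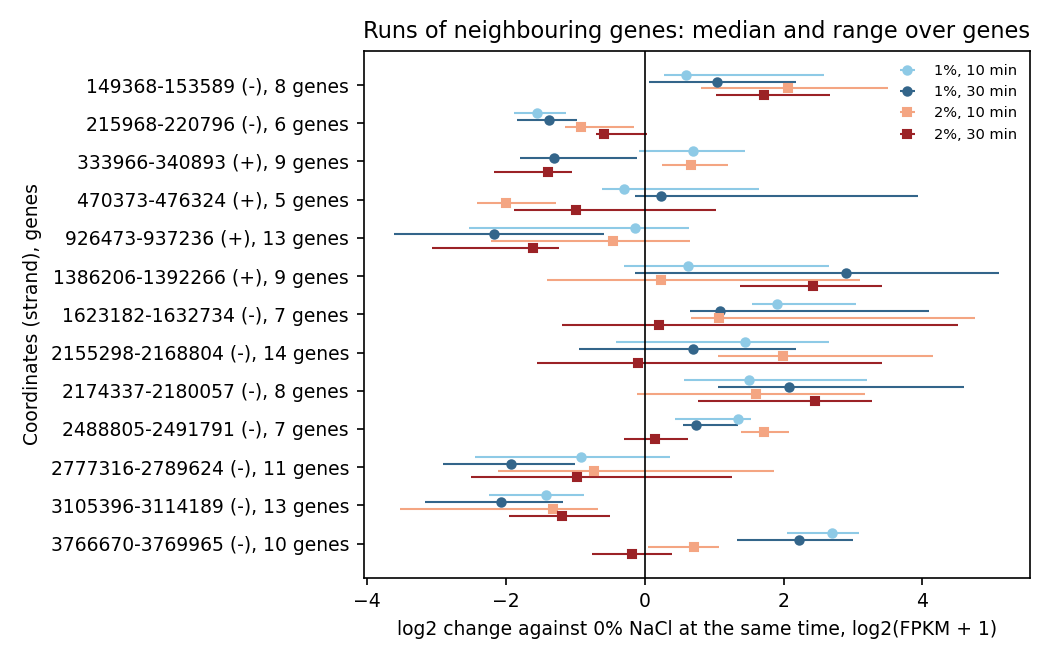
Points give the median log2 change, and lines the range, over the genes of each run, at 1% and 2% NaCl against 0% at 10 and 30 min. The 10 genes at 3766670 to 3769965 lay higher at 1% than at 2% NaCl at both times.

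Further features and those with sRNA IDs rose more often than gene models. At 2% NaCl and 30 min, 223 of 310 tested further features (71.9%) and 56 of 83 sRNA features (67.5%) rose, against 699 of 3963 gene models (17.6%; Fisher's exact test, two-sided, adjusted over 16 tests, p = 8.41e-87 and 2.20e-22, with features that are not independent replicates). At 1% NaCl and 10 min the shares were 62.3%, 59.0% and 17.3%. Of the 360 further features, 98.1% overlap another feature on the opposite strand by at least 20 bases. In 298 pairs with an overlapped gene, 236 further features were called at 2% NaCl and 30 min. Of these, 207 shared the call of that gene and 0 had the opposite call. Much of the rise of this class may thus restate that of the overlapped genes, which the comparison with all gene models does not allow for. The 2 most abundant features, Novel00327 (3752594 to 3752950, plus strand) and Novel00328 (3752595 to 3752950, minus strand), named after their values were seen, lie opposite each other. Novel00327 took 15.1 ± 2.78% of the reads (SD, n = 9) at 0% NaCl and 1.90 ± 0.598% (SD, n = 12) with NaCl (exact permutation test, two-sided p = 3.40e-06, the smallest the 293930 splits can give). Its log2 change of -2.34 at 2% NaCl and 10 min had an SE of 2.76 and an adjusted p of 0.491 in the limma fit. The trend of spread over level in that fit is thinly supported at such levels. In limma without that trend, chosen after the data were seen, the SE was 0.51 and the adjusted p 0.00101. At 1% NaCl and 30 min, however, the log2 change was -0.83 with an adjusted p of 0.152, also without the trend. The lower share of reads is thus not matched by a called fall in FPKM in every NaCl group. The share does not depend on the scaling, while FPKM does. At 30 min, 1 read in a feature of 1 kb was worth a mean of 0.238 FPKM at 0% NaCl and 0.689 FPKM at 1% NaCl. The mean share of reads went there from 13.7% to 2.14%, and the mean FPKM from 231238 to 120745.

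Dose was compared directly at each time. At 10 min, 664 features were higher and 645 lower at 2% than at 1% NaCl. Novel00213 (2397941 to 2398139, minus strand) was higher by 5.86 (SE 0.34) and its neighbour Sphingomonas.melonisTY_GM002409 (2398173 to 2398385) by 5.67 (SE 0.37); the latter reached 3051 ± 367 FPKM at 2% against 61.8 ± 23.2 FPKM at 1% (SD, n = 3 each). Lower at 2% were Sphingomonas.melonisTY_GM003673 (3709786 to 3711993, minus strand) at -4.33 (SE 0.40) and Sphingomonas.melonisTY_GM004079 (4111762 to 4113849, minus strand) at -4.20 (SE 0.31). At 30 min, 524 features were higher and 805 lower at 2%. Sphingomonas.melonisTY_GM002035 (2019238 to 2019327, minus strand) and Sphingomonas.melonisTY_GM002974 were higher by 4.74 (SE 0.98) and 4.09 (SE 0.79), with at most 3 reads per library at 1%. Sphingomonas.melonisTY_GM003528 (3535804 to 3535887) and Sphingomonas.melonisTY_GM003531 (3537719 to 3539752), both on the plus strand, were lower by 4.98 (SE 0.92) and 4.60 (SE 0.31). The former rested on 44 to 64 reads per library at 1% and 1 to 5 at 2%. The TPM rescale gave 897 higher and 416 lower at 10 min, and 1665 and 255 at 30 min.

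The lists for both doses overlapped. At 10 min, 512 features rose and 111 fell at both doses, where independent lists of these sizes would share 209 and 37.5, and 54 went opposite ways. At 30 min, 751 rose and 184 fell at both, against 260 and 106 for independent lists, and 25 went opposite ways. These counts hold for the scaling of the main fit alone. In the TPM rescale fewer features than 751 rose at 1% NaCl and 30 min, and falls outnumbered rises at each dose and time. Both doses were set against the same 3 control libraries, and simulated unchanged groups gave no shared call in 100 simulations but a median r of 0.578 at 10 min and 0.461 at 30 min. Observed r was 0.58 and 0.758, with covariances of 0.982 and 1.86 against simulated covariances of 0.0588 and 0.0394. The 3 controls were too few to split, so the part of the overlap that comes from them was estimated by these simulations alone. Lists that differ in both dose and time share no library: 697 features rose and 97 fell at both 1% and 10 min and 2% and 30 min (208 and 33.8 for independent lists; 17 went opposite ways; r = 0.778), and 534 rose and 144 fell at both 2% and 10 min and 1% and 30 min (261 and 117; 119 opposite; r = 0.427). Across times at 1 dose, which also share no library, 844 features rose and 260 fell at both times at 1% NaCl (246 and 81.8 for independent lists), and 685 rose and 235 fell at 2% (221 and 48.3). All NaCl groups had a wider mean spread of gene values than those at 0% NaCl, which the counts for independent lists do not allow for.

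The effect of NaCl differed between 30 and 10 min for 341 features at 1% and 543 at 2%. At 1%, it was higher at 30 min for 237, led by the neighbours Sphingomonas.melonisTY_GM003531 and Sphingomonas.melonisTY_GM003532 (3539765 to 3540334, plus strand). The first went from 46.4 ± 24.3 FPKM at 10 min to 1390 ± 142 FPKM at 30 min, and from 60.9 ± 3.07 to 54.5 ± 7.11 FPKM at 0% NaCl (SD, n = 3 each). For 104 features it was lower at 30 min. At 2%, the effect was higher at 30 min for 306 features and lower for 237. Sphingomonas.melonisTY_GM001404 (1333875 to 1335038, minus strand) went from 610 ± 203 FPKM at 10 min to 49.99 ± 0.646 FPKM at 30 min at 2% NaCl, while at 0% it went from 213 ± 40.2 to 625 ± 334 FPKM (SD, n = 3 each). The count at 1% depended on single libraries: it was 694 without replicate 3 of 1% NaCl at 10 min, 219 without replicate 3 of 1% NaCl at 30 min and 226 without replicate 1 of 0% NaCl at 10 min. With the spread covariate the counts were 547 at 1% and 820 at 2%, and after subtraction of a background 468 and 1233. In the TPM rescale the effect was higher for 132 and lower for 340 at 1%, and higher for 294 and lower for 394 at 2%.

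Without added NaCl, few features changed over time in the main fit. At 10 min against 0 min, 13 rose and none fell, 237 having an unadjusted p under 0.05; limma-voom on the recovered reads gave 18, all higher. Novel00024 (161616 to 161823, plus strand) and Sphingomonas.melonisTY_GM001406 (1336212 to 1338836, minus strand) rose by 2.59 (SE 0.42) and 2.48 (SE 0.34), the latter from 169 ± 54.7 to 928 ± 213 FPKM (SD, n = 3 each). At 30 min these 13 lay between -0.73 and 0.49 of their 0 min values on the log2 scale. Of these 13, 11 counted as lower at 2% NaCl at 10 min, and 12 had a higher 2% effect at 30 than at 10 min, so their salt contrasts carry the move of the control; against the same raised control 4 of the 13 rose at 1% NaCl at 10 min, and 9 rose at 1% at 30 min against 0% at 30 min. In the TPM rescale 38 features rose and 31 fell; the count was 25 when only the 2 groups compared were fitted, 69 with the spread covariate and 159 after subtraction of a background. At 30 min against 0 min limma called 0 features; 57 had an unadjusted p under 0.05, and limma-voom called 0, the TPM rescale 4, the spread covariate 8 and the subtraction 50.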

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

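The tests with the spread covariate, the subtraction of a background and the windows along the sequence were chosen after the results were seen. The effect of NaCl differed between 30 and 10 min, by a test of the difference itself, for 341 features at 1% and 543 at 2%. At 1%, Sphingomonas.melonisTY_GM003531 and Sphingomonas.melonisTY_GM003532 had effects higher at 30 min by 5.22 and 4.59 (log2), and Sphingomonas.melonisTY_GM002974 and Sphingomonas.melonisTY_GM004053 effects that differed by -4.64 and -3.54, the last with no read listed in the 3 libraries of 1% NaCl at 30 min, so that its size depends on the pseudocount. At 2%, Sphingomonas.melonisTY_GM002729 (2711599 to 2713833, plus strand) and Sphingomonas.melonisTY_GM003582 (3602174 to 3602599, minus strand) differed by 4.99 and 4.45, and Sphingomonas.melonisTY_GM001404 and Novel00145 (1332294 to 1332702, minus strand) by -4.96 and -3.82. The first of these went from 173 ± 54.9 FPKM at 0 min to 787 ± 166 FPKM at 10 min and 136 ± 27.0 FPKM at 30 min at 0% NaCl, and the second from 350 ± 131 to 938 ± 127 and 222 ± 95.5 FPKM (SD, n = 3 each). At 2% NaCl they went from 141 ± 18.5 to 825 ± 323 FPKM and from 815 ± 191 to 4156 ± 1774 FPKM between 10 and 30 min (SD, n = 3 each), so both differences hold a move of the control and one of the NaCl libraries. When what is left after additive effects of NaCl and time was reassigned among the 12 libraries, 2 of 100 assignments, the real one included, gave as many features at 1% NaCl (highest other 1160 against 341) and 2 of 100 at 2% (highest other 558 against 543). The share is under 0.05 for both, yet the 1160 features of 1 reassignment point to a structure among the libraries, whose cause was not tested.

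The wider spread of gene values in libraries with NaCl was weighed for the calls of NaCl against 0%. Most calls at 2% NaCl kept their direction and threshold under each adjustment taken alone. At least 72.6% did so with the spread as a covariate, and at least 60.4% after subtraction of a background. The bounds for these shares were also set after the results were seen. The covariate thus does not account for most of these calls. Subtraction turned the balance of calls to falls, and the 20th percentile may hold expressed genes, so a background is not excluded. For 1% NaCl the lowest shares were 36.0% and 39.2%, between the bounds set for them. For the calls at 1% as a whole, these tests therefore cannot tell spread and NaCl apart. The mean spread was wider than at 0% NaCl at both doses, so this alone does not set 1% apart from 2%. Across 42 windows of 100 kb, the lower quartile of gene values at 0% NaCl correlated between genes of the plus and the minus strand (Spearman's rho 0.721, permutation p = 1e-05, the smallest that 100000 permutations can give; 0.652 without the 3 lowest windows). This used 0% NaCl libraries alone, so it cannot show whether a background of reads, as from DNA, was larger there than with NaCl. The 20th percentile of gene-model FPKM was higher at 0% NaCl, at 48.3 ± 5.28 FPKM (SD, n = 9) against 29.2 ± 9.14 FPKM (SD, n = 12) with NaCl. As it may hold expressed genes, it cannot tell a larger background from a change of those genes. Such a background and a response of the cells to 1% NaCl stay open, and such a background stays open at 2% too.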

How the results depend on the processing

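Alternatives named in the methods as chosen after seeing the data are the covariate, the subtraction, limma-voom, no mean trend and gene models alone. Both pseudocounts, both filters, median-of-ratios factors, no limit on the fold, limma-voom and no mean trend left every total within 1.5 times. The median-of-ratios factors move nothing by construction, and the 4 alternatives for gene lists were not run, because no list could be matched. In the TPM rescale, 2495 features changed at 1% NaCl and 10 min, 3385 at 1% and 30 min, and 69 and 4 over time at 0% NaCl (10 and 30 min). With the groups of the contrast alone, 25 changed at 0% NaCl and 10 min, and with gene models alone 7, where fewer features were tested. The spread covariate gave 752 and 1100 features at 1% NaCl (10 and 30 min), 547 and 820 for the difference between times (1% and 2%), and 69 and 8 over time at 0% NaCl. Subtraction of a background gave 2503 at 2% NaCl and 30 min, 880 for 2% against 1% at 30 min, 1233 for the difference between times at 2%, and 159 and 50 over time at 0% NaCl, and 299 higher and 1521 lower at 1% NaCl and 10 min. The counts of the TPM rescale differ from the main fit only through each library's sum of FPKM. For the other counts the cause was not tested. With 1 library left out, 1% NaCl at 10 min gave 875 to 2044 features and the difference between times at 1% gave 219 to 694, and the other totals stayed within 1.5 times; the falls at 1% NaCl and 10 min, 338 in the main fit, ranged from 130 to 900.

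No label says that the replicate numbers pair the samples, and the main fit did not use them. Deviations of same-numbered libraries correlated by -0.413 to 0.81 (mean 0.271, against -0.129 for different numbers). As 14 of 21 libraries correlated best with their own number, the numbers may carry a shared structure, whose cause was not tested. Every pair lay above 0.1 for 2% against 0% NaCl at 30 min and for 0% NaCl at 30 against 0 min, where the block moved neither count by over 1.5 times. With the replicate number as a block, 547 features instead of 341 differed between times at 1% NaCl and 43 instead of 13 changed at 0% NaCl and 10 min; other totals stayed within 1.5 times, while the falls at 1% NaCl and 10 min went to 563. Of the 34 named changes none turned its direction; 8 fell below the threshold after subtraction, 10 of 252 values did so with a library left out, and the planned settings lost 2 or fewer each. Falls from under 50 reads are limited by depth.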

Other observations

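The test of a delay was set before its result was seen, and those of opposite-strand features and of the runs after. Of the 4356 tested features, 429 rose and 52 fell in all 4 contrasts of NaCl with 0%, and 146 rose in 1 and fell in another. These counts hold for the scaling of the main fit alone. Fewer features than 429 rose at 1% NaCl and 30 min in the TPM rescale, and at 1% and 10 min after subtraction of a background. Some neighbouring genes not described above also moved together. Along 149368 to 153589 (minus strand), 8 genes rose at 2% NaCl and 30 min by a median log2 of 1.72, and 6 of them at 10 min (4 and 5 in the TPM rescale); at 1% and 30 min their median of 1.05 turned to -0.73 in the TPM rescale. At 470373 to 476324 (plus strand), 5 genes fell at 2% NaCl and 10 min by a median of 2.00 on the log2 scale, and all 5 were lower at 2% than at 1% at both times; in the TPM rescale 4 of 5 were at 10 min and 2 of 5 at 30 min, where the median went from -1.73 to -0.74. At 0% NaCl these genes stood higher at 10 than at 0 min by 0.04 to 1.47 (median 0.30, 0 called), so part of the fall may be a move of the control. At 1623182 to 1632734 (minus strand), 7 genes rose at 1% NaCl and 10 min by a median of 1.91, which fell to 0.89 (3 of 7 still called) with the spread as a covariate, and at 30 min their median of 1.09 turned to -0.70 in the TPM rescale. At 215968 to 220796 (minus strand), 6 genes fell there by a median of 1.55, of which 0 kept the call with the spread as a covariate.

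Further features, those with IDs such as Novel00327, changed with the gene on their opposite strand. Over 298 pairs, log2 changes had a Spearman's rho of 0.759 to 0.883 with the overlapped gene and 0.291 to 0.419 with the nearest gene that they did not overlap; the smallest difference over the 4 contrasts was 0.368, and no pair was called in opposite directions. Reads of the gene counted for the feature opposite it would give this pattern. Transcription from both strands together stays open, since the strand setting is not stated. Novel00327 and Novel00328 cover nearly the same bases on opposite strands. The second stood at 0.342 to 0.414 of the FPKM of the first in every library, so for this pair the counting did not give the same reads to both.

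That many features stood higher at 1% than at 2% NaCl may reflect a response at 2% that ran behind. Changes at 2% NaCl and 30 min against 0 min, which share no library with the others, had r = 0.751 across features (not independent replicates) with those at 1% and 10 min and 0.723 with those at 1% and 30 min. The difference of 0.0278 lay between the bounds set beforehand, and without replicate 1 of 1% NaCl at 10 min it was -0.000836, so this stays open.

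For each contrast of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split gave 1264, 1466, 2210 and 1414 features for NaCl against 0% (1% and 2% at 10 min, then at 30 min), where 1 of 10 splits reached each count and the highest other gave 0. For 2% against 1% it gave 1309 at 10 min and 1329 at 30 min, with 1 and 0 as the highest others. At 0% NaCl it gave 13 at 10 min (highest other 0) and 0 at 30 min, as all 10 splits did. For the F-tests, 1 of 100 splits, the real one, gave as many as 2764 at 10 min (highest other 1843) and 3356 at 30 min (highest other 1929). The share is under 0.05 for both, which takes the libraries as exchangeable and makes chance unlikely without excluding it.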
